A study of Glycine max with 54 samples.

How the data were processed

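Total RNA of whole developing soybean seeds was hybridized to Affymetrix soybean arrays, 1 array per sample: 54 arrays in 18 groups of 3. Per the labels, the plants grew in Minnesota. In 2007, per the labels, each line was a single row with 3 samples per stage. In 2008 each line had 3 replicates planted at different times in randomized blocks, with samples from both rows of a replicate pooled. Per the labels, seed lengths of 2, 3.5 and 5-6 mm correspond to stages R4, R5 and early R6. The recombinant lines were grown as 1 high and 1 low yield line, so that a difference between them belongs to those lines and not to yield in general. The label of low yield line 3.5 mm replicate 3 names the low yield line in its title and the other line in its description; the title was used.

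The deposited values are on the log2 scale. Per the submitters' processing notes the authors used GCRMA, without a stated version. The values show 3 sets of 18 arrays processed apart: the parents of 2007 and of 2008 each have a common lowest value (1.96 in both, differing in the third decimal), and the recombinant lines have none (lowest value -1.56). Levels of genes are therefore compared only within a set, apart from the line scores of the parents and a test of the separate normalization itself. Because of this the planned comparisons of 2008 with 2007 in the parents and of each recombinant line with both parents were not run. Contrasts of differences taken within a set were run. A difference from a value at the floor or under the filter is not exact.

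Control probe sets were left out (126 Affymetrix and 48 ribosomal RNA of 37744), and 26482 probe sets with a log2 value of 5 or more in at least 3 arrays were tested. The given annotation matched 8677 probe sets to 1 gene, 370 to several and 28523 to none; 6958 tested probe sets had 1 gene (5100 genes), and 1248 of these (804 genes) had a descriptive symbol. Most tested probe sets therefore have no name here. With R 4.3.3 and limma 3.58.1, 1 model with a mean for each of the 18 groups was fitted to all arrays. Contrasts were tested with eBayes, and p values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Stage contrasts average 6 combinations of line and year, and parental contrasts average both years.

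Named genes were chosen by a rule: with 1 probe set per gene (the highest mean signal), the 8 largest changes each way among those called with the same sign in every combination of stage, line or year. It adds up to 4 called members of each list, the 3 largest each way for changes of a difference, and the 5 strongest calls shared by parents and recombinant lines. This rule, the comparisons, the filter and the list topics were set before the data were examined. The lists themselves were rewritten by gene symbol, and 6 families (WRKY, MYB and bZIP factors, GASA peptides, aquaporins and glutathione S-transferases) were added, after the annotation had been seen and before any test, because the annotation holds no product descriptions. Lists were tested with camera (correlation preset at 0.01, and again with an estimated one) and with fry; lists of under 5 measured genes were only counted. Seed coat, vegetative storage and photosynthesis lists stand for tissues a whole seed sample may hold, and no cell type was inferred from them.

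The pipeline was tested on simulated data with known changes added: at a log2 change of 1 it recovered 88.1% for Archer against Minsoy, 85.1% for the recombinant lines and 92.5% for the stages. At 0.5 it recovered 64.2%, 38.8% and 70.1%. Over the calls at all sizes together, 2 included, 4.00%, 4.52% and 4.92% were false. The simulated noise was normal and independent between probe sets, without a floor or out-of-place arrays. These shares therefore need not hold for the real arrays. Per the labels the replicates of 2008 are blocks planted 1 to 2 weeks apart, so their numbers pair the arrays of that year. Residuals of Archer and Minsoy arrays with the same number correlated between -0.25 and 0.48 in 2008. For 2007 the labels give no meaning to the numbers. There the correlation was over 0.1 in all pairs of the parents at 3.5 mm (0.25 to 0.40) and 5-6 mm (0.19 to 0.55) and of the recombinant lines at 3.5 mm (0.26 to 0.51), but not in all pairs elsewhere (parents at 2 mm -0.47 to 0.10). The fit given has no block, and blocks are alternatives. Stage scores used 200 probe sets each way chosen in the other sets, and line scores used 100 markers. Those of the recombinant lines were chosen without the doubted arrays, after the data had been seen, because a first version that kept them gave compressed scores.

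Alternatives were: no filter or one at log2 7, quantile normalization or median centring over all arrays, a replicate block, a trended and robust eBayes, array weights, 1-gene probe sets only, only the arrays of a comparison, 1 year only, and leaving out each array. For lists they were an estimated correlation or every probe set of a gene. Chosen after seeing the data were fits without 4 arrays whose profile went against their label, with the most alike pair averaged, and with the actin 3 prime to 5 prime difference as a covariate. limma's default array weights stopped before converging and gave still larger counts. Weights were therefore estimated gene by gene, also a choice made after seeing the data. Blocks within set and stage and with 2008 arrays only, and the count of line differences that run against the change with stage, were added after all results had been seen. Every called result was compared with other splits of the arrays, 100 drawn at random, or all 10 where only 3 arrays face 3.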

Results

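Developing seeds of 4 soybean lines were profiled: the varieties Archer and Minsoy, and a high yielding and a low yielding recombinant inbred line from their cross. Seeds were taken at lengths of 2, 3.5 and 5-6 mm, with 3 arrays for each line, stage and year. The parents were grown in 2007 and 2008 and the recombinant lines in 2007. Values are deposited log2 signals, and differences are given as log2 differences with their standard error (SE).

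The largest changes among the named genes between 2 mm and 5-6 mm seeds were rises (18 arrays at each stage). The transcript of GY1, a glycinin storage globulin, rose by 8.76 (SE 1.57, adjusted p = 9.34e-06). Its mean went from 1.96 (SD 0) in the 2 mm parental seeds of 2007, the floor of the scale, to 13.79 (SD 5.82) at 5-6 mm (6 arrays each), where Archer replicate 1 was still at the floor. In the high yield line, normalized in another set, it was at 11.25, 11.35 and 5.64 in the 2 mm arrays. At the middle seed length it was at 1.63, 9.79 and 11.39 in that line, and at 5-6 mm at 14.6, 14.3 and 15.5. Levels are not comparable between sets, so these values do not show an earlier rise in this line than in the parents. The 2S albumin gene GM2S-1 rose by 7.95 (SE 1.17, adjusted p = 3.55e-07). PM34, a seed maturation protein, rose by 7.83 (SE 0.77, adjusted p = 1.42e-10), FAD2-1A, the oleate desaturase of seed oil, by 7.80 (SE 0.88, adjusted p = 2.14e-09). LOX2, a seed lipoxygenase, rose by 8.28 (SE 1.34, adjusted p = 1.84e-06). The Bowman-Birk type inhibitor D-II rose by 8.39, the vacuolar thiol protease homologue P34 by 7.79 and the Kunitz inhibitor KTI1 by 7.48. Among the genes that fell, GASA6, of the gibberellin-regulated GASA peptides, fell by 5.69 (SE 0.54, adjusted p = 8.46e-11), the cytokinin oxidase CKX3 fell by 4.91 (SE 0.56, adjusted p = 2.7e-09). The vegetative lipoxygenase LOXB1 fell by 4.49 and XTH1, a xyloglucan endotransglucosylase of the cell wall, fell by 3.34. BZIP50, the protein kinase gene SPK-1 (-2.81), NAC34 (-2.74) and GER2 (-2.74) fell as well. Each of these 16 genes had the same direction in the 6 pairs of stage means, one pair for each line and year, as the rule that chose them required. GY1, GM2S-1, LOX2, D-II, P34 and KTI1 lie at the floor in the 2 mm parental seeds of 2007, PM34 near it there (mean 2.36, SD 0.20) and GER2 near it in the 5-6 mm ones of 2008. Means at 2 or 5-6 mm also lie under the filter level of log2 5 in at least 1 set for FAD2-1A, BZIP50, SPK-1 and NAC34 and, below, for IFS1, IFS2, LOX3 and GASA12. The sizes of these changes are not exact.

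**Figure D1:**
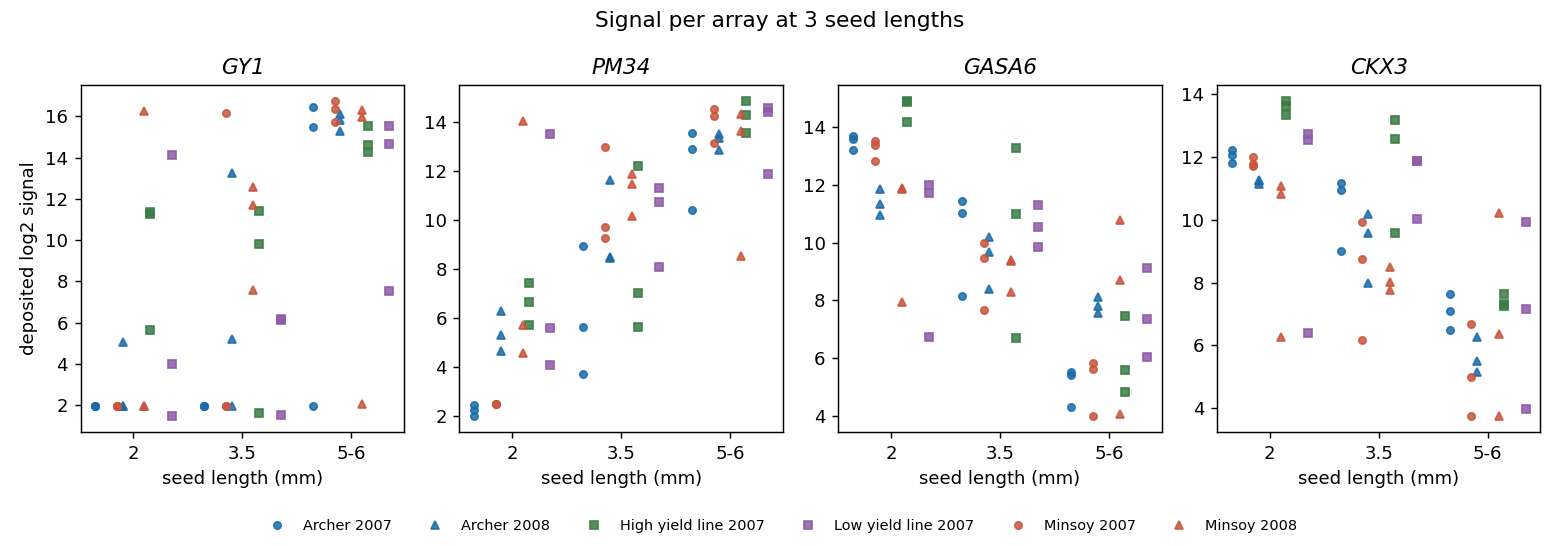
Deposited log2 signal (vertical axis) of GY1, PM34, GASA6 and CKX3 against seed length in mm (horizontal axis), 1 point per array, coloured by line and shaped by season and set. GY1 and PM34 rise and GASA6 and CKX3 fall, with single arrays out of place, among them the Minsoy 2008 replicate 1 arrays at 2 mm and at 5-6 mm.

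By gene list, 11 of 12 measured storage globulin and albumin genes rose and 0 fell (median change 5.09; camera adjusted p = 0.000609, adjusted p = 0.456 with an estimated correlation). Of the late embryogenesis and seed maturation genes, 28 of 30 rose and 1, LEA-2, fell (median 3.21; adjusted p = 9.42e-09, adjusted p = 0.425 with an estimated correlation). PM30 rose by 6.01. Protease inhibitors and other seed defence proteins: 9 of 10 rose (median 3.56; adjusted p = 0.00219, adjusted p = 0.456 with an estimated correlation). In the list of fatty acid and triacylglycerol synthesis 13 of 21 rose and 4 fell (median 0.37; adjusted p = 0.0112, adjusted p = 0.415 with an estimated correlation). WRI1B, of the WRINKLED1 regulators of fatty acid synthesis, rose by 2.37, while the desaturase genes FAD2-2 (-0.80) and FAD2-3 (-0.47) fell. Of 7 seed regulators of transcription 5 rose, NF-YA13 by 2.92 and MFT by 2.51, and 2 fell (adjusted p = 0.0273, adjusted p = 0.409 with an estimated correlation). In the photosynthesis list 11 of 15 rose and 3 fell (median 0.77; adjusted p = 0.00585, adjusted p = 0.409 with an estimated correlation). The stay-green genes SGR1 and SGR, of chlorophyll breakdown, rose by 2.89 and 2.83, and RCABETA, a Rubisco activase, fell by 1.01. Camera called these 6 lists with its preset correlation and 0 with an estimated one. fry, which tests whether the genes of a list change and does not compare them with other genes, called every tested list for changes in either direction. By direction it called all but amino acid supply (adjusted p = 0.204), heat shock (0.593) and GASA peptides (0.254). The counts adjusted over the list alone were the same for all 6.

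The other lists were mixed and were not called by camera (lowest adjusted p = 0.114, for sucrose and starch). Both isoflavone synthase genes rose, IFS2 by 4.84 (SE 0.59) and IFS1 by 4.83 (SE 0.64). In their flavonoid list 12 of 32 rose and 11 fell, among them the chalcone synthase gene CHS8 (by 1.40) and the anthocyanidin reductase gene ANR1 (by 0.94). In that list the median (-0.05) and the mean (0.69) differ in sign and the test pointed up, as in the MYB list (-0.02 and 0.18) and the GASA list (-0.01 and 0.13); in the photoperiod list (-0.17 and 0.15) it pointed down. The lipoxygenase and beta-amylase list was divided between the seed genes LOX2 and LOX3, which rose by 8.28 and 7.17, and vegetative genes such as VLXB, which fell by 2.30. In it 4 of 9 rose and 5 fell, with a median of -1.01, a mean of 1.14 and a test that pointed down. Sucrose and starch genes rose in 9 of 13 cases and fell in 4, with the transporter gene SWEET17 up by 2.11 and the phosphoglucomutase gene PGM lower by 0.82 (log2 change -0.82). Cell wall genes (5 of 10 rose, 2 fell), amino acid supply (8 of 16 rose, 5 fell; 9 and 5 adjusted over the list alone) and photoperiod genes (3 of 10 rose, 4 fell) were mixed. Of 15 plant hormone genes 7 rose, among them GAI2 (3.63) and GA20OX3 (2.62), and 4 fell. The defence list had 1 of 10 genes rise and 5 fall, and the heat shock list 4 of 17 rise and 6 fall, among them HSP17.5-E (-2.29). Among regulators, 2 of 20 WRKY genes rose and 11 fell, 16 of 44 MYB genes rose and 11 fell, and 9 of 47 bZIP genes rose and 22 fell. Of the small proteins 6 of 14 GASA genes rose, GASA12 by 5.27, while 4 fell. Aquaporins (7 of 18 rose, 4 fell) and glutathione S-transferases (7 of 19 rose, 3 fell) were also mixed. Lists of under 5 genes were counted only. Of the seed coat markers HPS (3.42) and the peroxidase gene Ep (2.19) rose and SCB1 fell by 0.31. Of the vegetative storage and lipoxygenase genes VSPA rose by 2.08, although another of its probe sets fell (-0.79), and 3 of 4 fell. Ep and HSP17.5-E had their direction in 4 and HPS and GA20OX3 in 5 of 6 pairs of stage means. The remaining short lists are cell cycle (both genes fell), ribosomal proteins (0 of 4 passed), histones (0 of 1, and 1 rose adjusted over the list alone) and oil body proteins (0 measured). The cell cycle gene CCS52 (-0.32) lost its call in 22 of 69 alternatives.

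Over all 26482 probe sets tested, limma called 16540 between 5-6 mm and 2 mm seeds at an adjusted p under 0.05 (6746 rose, 9794 fell), 3401 of them by 2-fold or more. From 2 to 3.5 mm 7335 were called (3760 rose, 3575 fell; 3438 and 3900 after quantile normalization) and from 3.5 to 5-6 mm 14614 (5782 rose, 8832 fell). Of the 3.5 mm arrays of the recombinant lines, replicates 1 and 3 also had the highest differences between the 3 prime and 5 prime actin probe sets, a sign of RNA quality: 3.07 and 2.96 in the high and 3.30 and 3.36 in the low yield line. Replicate 2 had 1.74 and 1.38, against means of 1.36 and 1.46 at 5-6 mm. Within single lines the calls between 5-6 mm and 2 mm were 11550 in Minsoy 2007, 7808 in Archer 2007, 2831 in Archer 2008, 10331 in the high and 81 in the low yield line. In Minsoy 2008 limma called 0, with 1435 at an unadjusted p under 0.05. The low yield and Minsoy 2008 groups hold arrays whose stage profile went against their label. With the 2008 arrays alone 1213 probe sets were called over both parents, and 7 with the planting replicates of that year as a block.

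Between Archer and Minsoy seeds the largest difference among the named genes was that of UGT708D1, a flavonoid C-glucosyltransferase (18 arrays of each line, mean of 3 stages). It was higher in Archer by 4.27 (SE 0.48, adjusted p = 1.2e-08). LAR1, the leucoanthocyanidin reductase of proanthocyanidin synthesis, was lower (log2 difference -2.69, SE 0.20, adjusted p = 2.6e-13). In 2008 the means were 8.93 (SD 0.38) in Archer and 3.31 (SD 0.64) in Minsoy for UGT708D1, and 9.34 (SD 0.50) and 12.27 (SD 0.67) for LAR1, 9 arrays each. In 2007 they were 9.98 (SD 0.29) and 7.05 (SD 1.89) for UGT708D1, with Minsoy arrays up to 9.90, within the range of Archer, and 9.14 (SD 0.81) and 11.59 (SD 0.70) for LAR1. BZIP130 (1.38), GSTZ3 (1.36), GLYI-17, BZIP48 (1.07), the calmodulin gene SCAM-4 (0.90), GASA21 (0.75) and AGL3L (0.54) were also higher in Archer; a second probe set of GSTZ3 was not called. Lower in Archer were PAP25, a purple acid phosphatase (-2.68, SE 0.42, adjusted p = 1.1e-05), and A1 (-2.52, SE 0.35, adjusted p = 1.48e-06), grouped here with the storage proteins although what its symbol stands for is uncertain. So were ICE4, of the ICE type bHLH factors (-1.88, SE 0.21, adjusted p = 1.44e-08), MYB185 (-1.72), NAC19 (-1.72), SWEET17 (-1.56) and GASA32 (-1.22). Each of these 16 genes had its direction in all 6 pairs of means for a stage and year, as the rule that chose them required. In 2007 Minsoy seeds of 2 and 3.5 mm had later stage scores than Archer seeds of the same length, as given below. Of 39 genes named between the parents 25 also changed with stage, and 21 of these ran the way this offset would set, lower in Archer where they rise with stage and higher where they fall. LAR1, A1, NAC19, SWEET17, GLYI-17, BZIP48, GASA21 and AGL3L are among them. PAP25, PM29, CHR4 and SIP1-3 ran the other way. For the 21 genes, apart from LAR1 and the 3 genes set apart below, a difference between the lines was not separated from the offset. In 2007 LAR1 was at most 10.02 in the Archer arrays and at least 10.62 in the Minsoy arrays, all stages included. In 2008 it was at most 10.10 in Archer and at least 11.38 in Minsoy. An offset in stage alone would not give this gap.

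**Figure D2:**
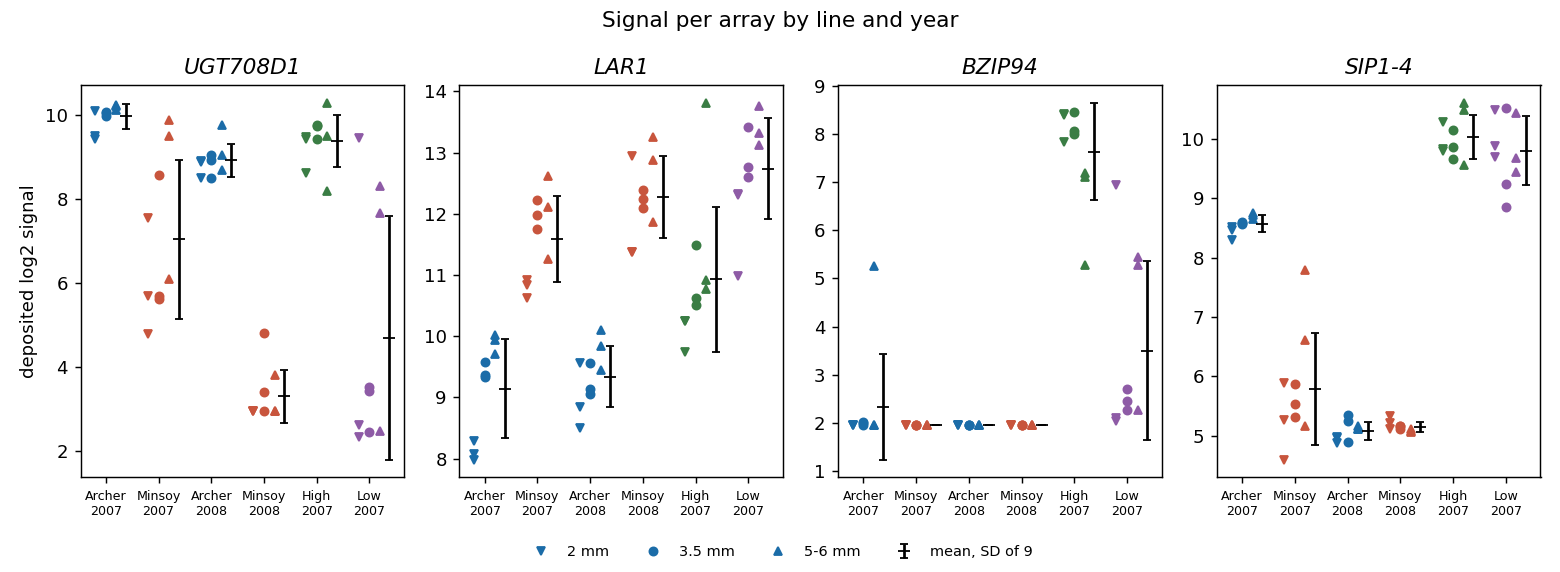
Deposited log2 signal (vertical axis) of UGT708D1, LAR1, BZIP94 and SIP1-4 by line and year (horizontal axis), 1 point per array with the shape giving the stage, and a black bar for the mean and SD of 9 arrays. UGT708D1 is higher and LAR1 lower in Archer and in the high yield line, and SIP1-4 separates Archer (mean 8.57) from Minsoy (5.78) in 2007 but not in 2008 (5.08 and 5.15).

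Among the gene lists, camera called late embryogenesis and seed maturation lower in Archer (median -0.96; adjusted p = 0.0109, adjusted p = 0.741 with an estimated correlation), although 26 of its 30 genes did not pass and fry did not call it (adjusted p = 0.156). This list rises with stage, and in 2007 Minsoy seeds of the same length had later stage scores. At 2 mm they were -1.84, -0.90 and -1.91 in Minsoy against -2.41, -3.09 and -2.25 in Archer, and at 3.5 mm 2.34, 1.86 and 3.13 against 0.42, 0.19 and 2.12. A difference between the lines at equal stage was not separated from this, for the list or for PM30, PM12, LEA-2, GS1GAMMA2, GDH1, LCL3, LHY, MYB68 and EDS1-2, given below. PRP2, HSF-35 and GSTU47, also below, kept their call in every alternative that tested them, 2008 arrays alone among these. Their differences ran from -1.26 to -1.02, -0.77 to -0.64 and -0.998 to -0.847, which argues against the 2007 offset as their only source. At 3.5 mm the Minsoy scores of 2008 were later too (2.15, 1.63 and 2.35 against 1.97, 1.33 and 0.71). By direction fry called GASA peptides and aquaporins (adjusted p = 0.00461 each) and flavonoids and glutathione S-transferases (0.0105 each). For changes in either direction it called these 4 lists and the MYB (4.56e-07) and bZIP (1.02e-05) lists. PM29 and LEA-2 (0.25) were higher and PM30 (-1.73) and PM12 (-1.40) lower. Of the 12 genes in the storage protein list only A1, of uncertain identity, passed (median -1.57 over the list; adjusted p = 0.0678). In the flavonoid list 4 of 32 genes were lower in Archer, LAR1 and the chalcone reductase gene CHR4 (-0.66) among them, and 0 were higher. Glutathione S-transferases had 1 higher and 5 lower of 19 (1 and 8 adjusted over the list alone), with GSTZ3 higher and GSTU47 (-0.92) and GSTa (-0.67) lower. GASA peptides had 1 higher and 3 lower of 14 (2 and 6 adjusted over the list alone), among them GASA14 (-1.14). The probe sets of GASA14 and GASA32 share a name stem, so the list may count the same signal more than once. Of 18 aquaporins 3 were higher, with SIP1-4 (1.36) and SIP1-3 (0.98) set apart by a difference in 2007 alone. MYB factors had 2 higher and 5 lower of 44, MYB68 by -1.15, and bZIP factors 3 higher of 47. The clock genes LCL3 (0.80) and LHY (0.34) were higher in Archer, the glutamine synthetase gene GS1GAMMA2 (-0.84) and the glutamate dehydrogenase gene GDH1 (-0.71) lower. Also lower were the heat shock factor gene HSF-35 (-0.72), PR-10 and the proline-rich cell wall protein gene PRP2 (-1.16). SWEET17 was the only 1 of 13 sucrose and starch genes, PRP2 of 10 cell wall genes past the threshold. The same holds for RCA11 (-0.21) of 15 photosynthesis genes (3 lower adjusted over the list alone) and ARF (-0.41) of 15 hormone genes. Of 10 defence genes EDS1-2 (0.57) was higher and PR-10 lower. In the defence, hormone and clock lists the medians (0.06, 0.01 and -0.03), the means (-0.02, -0.03 and -0.02) and the tests (up, down and up) differ in sign. Fatty acid synthesis, protease inhibitors, lipoxygenases, seed regulators, WRKY factors, vegetative storage, ribosomal proteins, histones, seed coat and cell cycle lists had 0 members past the threshold. Adjusted over the list alone, seed coat had 1 higher and 1 lower and cell cycle 1 higher. Oil body proteins had 0 measured. Other probe sets of SWEET17, PM30, PM12, LHY and GSTU47 (-0.07 and -0.32 for the last) and 1 of GDH1 had the same sign and were not called. EDS1-2, at levels under the filter, was not called with the arrays of a stage paired by number. PM29, RCA11, EDS1-2 and SIP1-3 had their direction in 4 of 6 pairs of means, and LEA-2, PM30, PM12, ARF, LCL3 and SIP1-4 in 5 of them.

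limma called 2630 probe sets between the parents (1327 higher and 1303 lower in Archer), 413 by 2-fold or more. The counts were 608 at 2 mm (363 higher, 245 lower), 616 at 3.5 mm (272 higher, 344 lower) and 1602 at 5-6 mm (811 higher, 791 lower). The last count ranged from 592 to 3946 when single arrays were left out. Of the 2630 calls 1705 were also called between 5-6 mm and 2 mm seeds, and 1346 of these (78.9%) ran the way the stage offset would set. At 3.5 mm the larger side flipped after quantile normalization over all arrays, to 383 higher and 301 lower. At 5-6 mm the larger side also flipped, to 919 higher and 935 lower. Within years 2406 were called in 2007 and 783 in 2008. In both years 434 were called, where independent calls would share 71.1, and 431 of these had the same sign. Both years use the same estimate of spread for each probe set, which alone can raise the number called in both. On markers chosen in 2007 the Archer arrays of 2008 had line scores from -0.03 to 0.07, where 0 is Minsoy and 1 Archer in 2007, and the Minsoy arrays of 2008 from -0.21 to -0.11. These scores are medians, so many of the markers lost most of their difference, and the mean over both years hides this. In 2007 each line stood in a single field row, so that line and row cannot be separated in that year. Without the 4 arrays whose profile went against their label, the 3.5 mm count was 1039 and the 5-6 mm count 3345. Minsoy 5-6 mm 2007 replicate 3, with a line score of 0.62 on markers chosen in 2008, was kept in that fit.

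In the recombinant lines the high yield seeds had more UGT708D1 (difference 4.69, SE 0.68, adjusted p = 7.54e-06, 9 arrays of each line) and more BZIP94 (4.13, SE 0.43, adjusted p = 1.77e-08) than the low yield seeds. Each recombinant line stood in a single field row, so that line and row cannot be separated. The SE and adjusted p values here measure the spread of arrays within groups and not that between rows. The mean BZIP94 signal was 7.63 (SD 1.01) in the high and 3.51 (SD 1.86) in the low yield line, where the arrays divide. In 2 mm replicate 1 and 5-6 mm replicates 1 and 3 of the low yield line UGT708D1 was at 9.46, 8.33 and 7.67 and BZIP94 at 6.95, 5.44 and 5.28. In its other 6 arrays they lay from 2.35 to 3.53 and from 2.05 to 2.71, under the filter level. The line scores of these 3 arrays were 1.003, 0.26 and 0.305, so the 2 differences rest on the other 6 and their sizes are not exact. The high yield line was also higher in VSPA, a vegetative storage protein (1.67, SE 0.50), NAC6 (1.60), BZIP130 (1.56), SCAM-4 (1.46), SGT3 (1.35) and the Kunitz inhibitor gene KTI-3 (1.17, SE 0.29). Of 5 further VSPA probe sets 1 was called (0.70) and 4 were not, and these differ in sign. It was lower in NAC27 (-2.37, SE 0.56, adjusted p = 0.00519; -0.64 and not called in a second probe set) and ICE4 (-2.10, SE 0.30, adjusted p = 6.41e-06). Also lower were NAC4 (-1.96), LAR1 (-1.81, SE 0.28, adjusted p = 2.28e-05), the invertase inhibitor gene CIF1 (-1.63), the stay-green gene SGR2 (-1.05), AOS1, the allene oxide synthase of jasmonate synthesis (-0.98), and PRP2 (-0.96). The probe sets of NAC27 and NAC4 share a name stem, so their signals may not be separate. These 16 genes had the same direction at all 3 stages, as the rule that chose them required. NAC6 (adjusted p = 0.0494) lost its call when most single arrays were left out. NAC6 and VSPA were not called with a replicate block. The low yield 2 mm arrays had later stage scores (4.91, -0.28 and -0.61) than the high yield ones (-2.44, -2.48 and -1.84). Of 33 genes named between the recombinant lines 22 also changed with stage, and 19 of these ran the way this offset would set, while VSPA, SGT3 and KTI-3 ran the other way. NAC27, NAC4, LAR1, CIF1, SGR2, AOS1 and PRP2 are among the 19, as are GA20OX3, GS1GAMMA2, LCL3, SWEET13, SWEET42, LAX11, MYB179, NF-YA05, IFR1, PRP3, EDS1-2 and GH1 below. For them, apart from LAR1, a difference between the lines was not separated from the offset. Low yield 2 mm replicates 2 and 3 had LAR1 at 12.33 and 12.31, above high yield 5-6 mm replicates 2 and 3 (10.76 and 10.92). An offset in stage alone would not give this. Low yield 2 mm replicate 1 (10.98) and high yield 5-6 mm replicate 1 (13.81), whose profiles went against their label, ran the other way. Second probe sets of CIF1 and, below, 1 of IFR1 had the same sign and were not called.

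Between the recombinant lines camera and limma called 0 gene lists, and 0 with an estimated correlation. fry called none by direction (lowest adjusted p = 0.143) and, for changes in either direction, the bZIP list alone (adjusted p = 8.78e-07). Single members passed. In the bZIP list 5 of 47 genes were higher in the high yield line (7 adjusted over the list alone) and 0 lower, and in the flavonoid list 3 of 32 were lower, LAR1 and the isoflavone reductase gene IFR1 (-0.67) among them. Cell wall genes PRP2 and PRP3 (-0.43) were lower (2 of 10; 3 adjusted over the list alone), and of the sucrose and starch list CIF1 and SWEET13 (-0.65) were lower and SWEET42 (0.54) higher. AMS1 (0.78), the only 1 of 12 storage protein genes past the threshold, and the defence genes DRR1 (1.06) and EDS1-2 (0.96) were higher, EDS1-2 at 1 of 3 stages. The hormone gene GH1 (0.30) was higher at all 3 stages. The gibberellin oxidase gene GA20OX3 (-1.46, lower at 2 of 3 stages), the auxin carrier gene LAX11 (-0.57), GS1GAMMA2 (-0.88), the aquaporin gene PIP2-10 (-0.89) and GSTa (-0.38) were lower. In the clock list LCL3 was higher (0.82) and LUXC lower (-0.69). NF-YA05 (-0.47, lower at 2 of 3 stages) of 7 seed regulators, SGR2 of 15 photosynthesis genes (2 lower adjusted over the list alone), MYB179 (-0.57) of 44 MYB genes, KTI-3 of 10 protease inhibitors (2 higher adjusted over the list alone) and VSPA of 4 vegetative storage genes were the members past the threshold in their lists. Adjusted over the list alone the counts higher and lower were 1 and 3 for sucrose and starch, 0 and 2 for amino acid supply, 2 and 1 for defence, 1 and 3 for hormones, 2 and 1 for the clock and 1 and 1 for seed coat. Medians (0.03, 0.04, 0.0024, 0.02 and -0.05) and means (-0.19, -0.04, -0.06, -0.02 and 0.02) differ in sign for the sucrose, heat shock, hormone, MYB and GASA lists, whose tests all pointed down. Seed maturation (30 genes), fatty acid (21), lipoxygenase (9), heat shock (17), WRKY (20), GASA (14), seed coat, cell cycle, ribosomal and histone lists had 0 past the threshold. Oil body proteins had 0 measured.

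limma called 1421 probe sets over the 3 stages (877 higher and 544 lower in the high yield line), 431 by 2-fold or more. Of 100 splits of these arrays, the real one included, 7 gave a count as large (highest other 7295), so chance is not excluded. By stage there were 2085 at 2 mm (1161 higher, 924 lower), 440 at 3.5 mm (261 higher, 179 lower) and 0 at 5-6 mm, where limma gave 1115 at an unadjusted p under 0.05. With single arrays left out they ranged from 966 to 2836, from 267 to 2650 and from 0 to 140. Without a filter the count at 3.5 mm rose and its larger side flipped, as given below. Of the 1421 calls 1016 were also called between 5-6 mm and 2 mm seeds, and 933 of these (91.8%) ran the way the stage offset would set. Each recombinant line grew in 1 field row. Without the 4 arrays whose profile went against their label the counts were 1831 over the stages, 1322 at 2 mm, 606 at 3.5 mm and 321 at 5-6 mm. With only the arrays of each comparison in the fit they were 448, 121, 59 and, by limma, 0 (1293 at an unadjusted p under 0.05). Low yield 5-6 mm replicates 1 and 3, with line scores of 0.26 and 0.305, were kept in these fits. Neither 0 nor 321 at 5-6 mm therefore rests on arrays that all score clearly as their line.

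**Figure D3:**
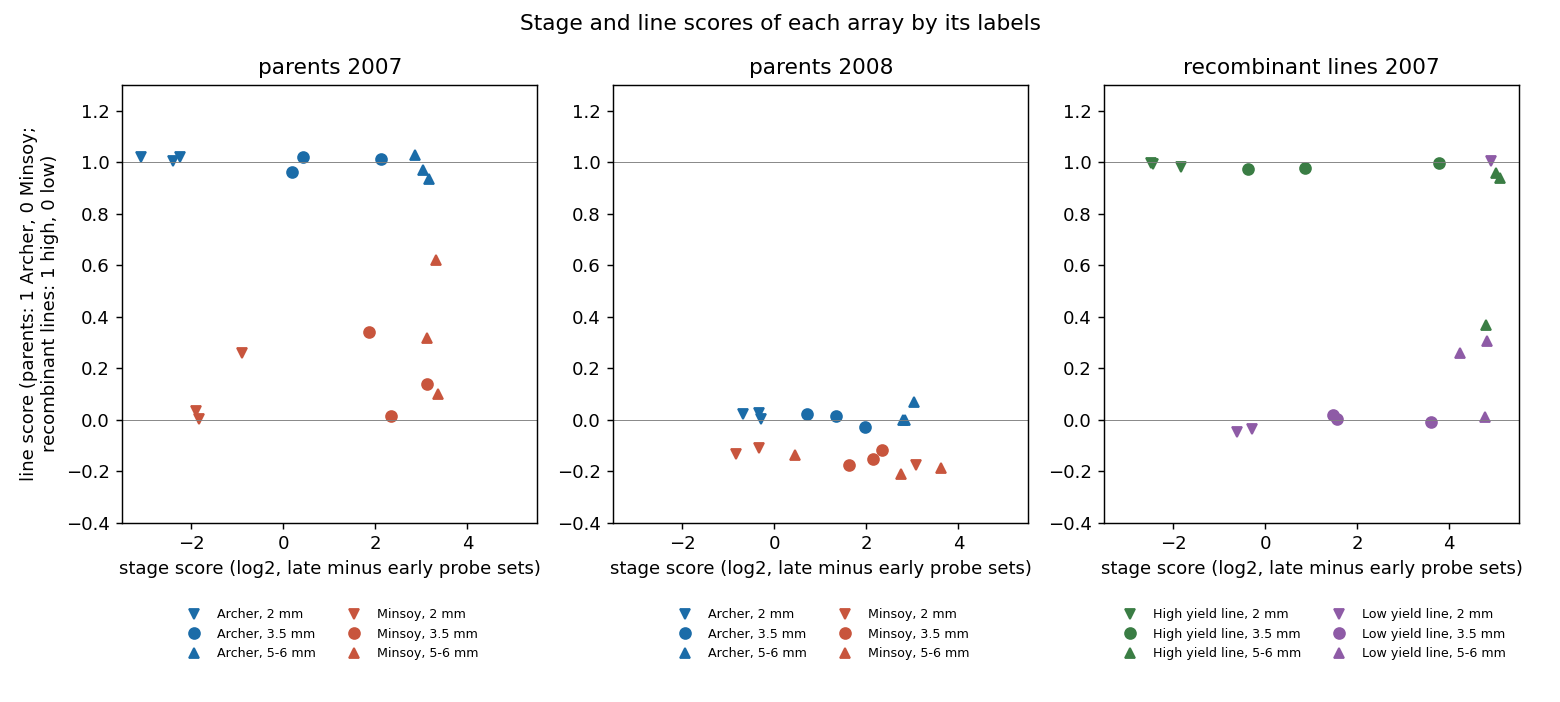
Line score (vertical axis, no unit; 0 for Minsoy or the low yield line, 1 for Archer or the high yield line) against stage score (horizontal axis, log2, late minus early probe sets chosen in the other sets), 1 point per array, with the 2008 arrays scored on markers chosen in 2007. Minsoy 2 mm 2008 replicate 1 has a stage score of 3.07 and low yield 2 mm replicate 1 one of 4.91, with the 5-6 mm arrays, and the 2008 Archer arrays have line scores from -0.03 to 0.07.

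**Figure D4:**
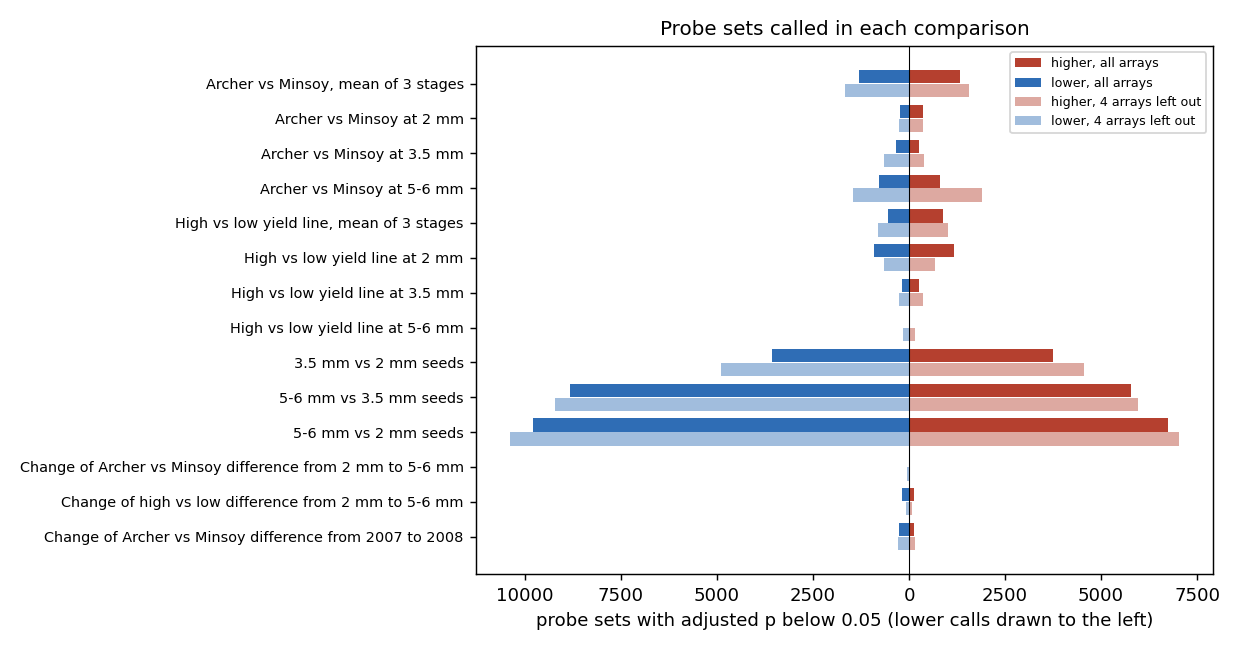
Number of probe sets called by limma at an adjusted p under 0.05 (horizontal axis) in each comparison (vertical axis), higher to the right and lower to the left, with all arrays (dark bars) and without the 4 arrays whose profile went against their label (pale bars). The stage comparisons give the most calls, 16540 for 5-6 mm against 2 mm with all arrays, and the high against low yield bar at 5-6 mm goes from 0 to 321.

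The parents and the recombinant lines, measured on separate arrays, shared calls. UGT708D1 (4.27 and 4.69) and BZIP130 (1.38 and 1.56) were higher in Archer and in the high yield line, and ICE4 (-1.88 and -2.10), LAR1 (-2.69 and -1.81) and PRP2 (-1.16 and -0.96) were lower in both. Of 2630 and 1421 calls 558 were common, where independent calls would share 141, and 535 of them (95.9%) had the same sign, Archer with the high yield line. At 2-fold or more 142 were common (6.72 from independent calls), 139 of them with the same sign (97.9%). In 2007 the 2 mm seeds of Archer and of the high yield line also had earlier stage scores than those of Minsoy and of the low yield line. This offset runs the same way in both comparisons, and of the 535 shared calls 337 were also called with stage, 303 of them (89.9%) the way it would set. Among the 9942 probe sets not called with stage 204 were common, where independent calls would share 37.7, and 198 of them had the same sign. Both comparisons use the same estimate of spread for each probe set, from the fit to all arrays. This alone can raise the number of shared calls above that of independent calls, but not the share with the same sign. No test that treats probe sets as independent was run on this overlap, since probe sets are not independent.

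The difference between the parents changed from 2007 to 2008 in genes that include the aquaporins SIP1-4 and SIP1-3. SIP1-4, a small basic intrinsic protein, had a mean of 8.57 (SD 0.14) in Archer and 5.78 (SD 0.94) in Minsoy in 2007, against 5.08 (SD 0.16) and 5.15 (SD 0.08) in 2008, 9 arrays each. The difference fell by 2.87 (SE 0.31, adjusted p = 4.22e-08). SIP1-3 did likewise: 11.89 and 9.91 in 2007, 9.26 and 9.28 in 2008 (difference fell by 1.99, SE 0.18, adjusted p = 4.1e-10). For MYB60 it fell by 1.05 (SE 0.28, adjusted p = 0.0384; not called with a replicate block, nor in its other probe sets). For NAC4 it changed by 2.21 in favour of Archer (SE 0.54, adjusted p = 0.0207). NAC4 rises with stage (1.93), and its 2007 difference (-1.24) ran the way the stage offset of that year would set. Its change was not separated from this. In all limma called 389 probe sets (131 with a more positive and 258 with a more negative difference in 2008), 202 by 2-fold or more, and 611 with only the parents' arrays in the fit.

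The difference between the recombinant lines changed from 2 mm to 5-6 mm in genes that differed at 2 mm (3 arrays a group). The 2 mm groups also differ in stage: the low yield line had later stage scores, as given above. The changes given here were not separated from this. DREB1, of the drought-responsive DREB factors, had means of 5.06 (SD 0.71) in the high and 9.78 (SD 1.58) in the low yield line at 2 mm. At 5-6 mm they were 11.56 and 11.31 (change 4.97, SE 0.89, adjusted p = 0.00147). AOS1 (10.19 and 12.33 at 2 mm; change 1.83, SE 0.42, adjusted p = 0.018) and NF-YA05 (8.99 and 10.27; 1.31, SE 0.31, adjusted p = 0.0199) went the same way. EDS1-2, a regulator of defence (5.59 and 2.51 at 2 mm; change -3.14, SE 0.58, adjusted p = 0.00188), was higher at 2 mm in the high yield line. So were the aldehyde dehydrogenase gene ALDH2C8 (9.93 and 7.86; -2.53, SE 0.58, adjusted p = 0.0179) and NIR, a nitrite reductase (4.42 and 2.33; -2.12, SE 0.31, adjusted p = 9.92e-05). In the high yield line the first 3 of these genes also rise and the other 3 fall with stage. The levels of NIR, and of EDS1-2 outside the high yield 2 mm group, lie under the filter level of log2 5, so the sizes of these changes are not exact. In all 312 probe sets were called (142 up, 170 down), 157 without the 4 arrays and 72 with only the arrays of the recombinant lines at these stages. Between the parents the same change was called for 15 probe sets (4 up, 11 down), no named gene among them, 83 without the 4 arrays and 691 without Minsoy 5-6 mm 2007 replicate 1.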

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

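The tests of exchanged and wrongly labelled arrays, pace of development, RNA quality, separate normalization, the 2007 Archer row and the scatter of called genes were chosen after the results were seen. The splits, the neighbour test and the test of Minsoy alleles were written down before their own results.

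A test of the difference itself picked out 3 counts: 15 probe sets whose parental difference changed from 2 mm to 5-6 mm, 312 whose high against low difference did, and 389 whose parental difference changed between the years. The genes among them are DREB1 (4.97), AOS1 (1.83), NF-YA05 (1.31), EDS1-2 (-3.14), ALDH2C8 (-2.53) and NIR (-2.12) for the recombinant lines by stage, and NAC4 (2.21), SIP1-4 (-2.87), SIP1-3 (-1.99) and MYB60 (-1.05) for the parents by year, as log2 changes of the difference. One signal lies outside the comparisons: the actin 3 prime minus 5 prime log2 difference averages 1.95 in the recombinant line arrays (range 1.22 to 3.36, n 18) against -0.56 in the 2007 and -0.33 in the 2008 parents. Since these arrays form their own separately normalized set, batch and line cannot be separated.

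Minsoy 2008 replicate 1 at 2 mm and at 5-6 mm is out of place: stage scores of 3.07 and 0.44, against means of -0.58 and 3.19 in the other arrays of their groups. An exchange of the 2 arrays has what it needs (3.07 for the array labelled 2 mm). A faster or slower development shared by both samples of that replicate is excluded, since the deviations are 3.64 and -2.75. A different pace in each sample was not tested. The actin difference gave no sign of poor RNA in the 2 mm array (-0.39, within -0.57 to -0.16 in 16 other 2008 arrays). For the 5-6 mm array (-0.10) RNA quality stays open. This rests on the actin probe sets alone. No biological explanation beyond a shared pace of development was tested.

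Among the recombinant lines, low yield 2 mm replicate 1 has a line score of 1.003 and a stage score of 4.91. An exchange with high yield 5-6 mm replicate 1 is excluded, as that array keeps the stage score of a 5-6 mm seed (4.80, against -0.28 and -0.61 in the low yield 2 mm arrays). A single wrong label of the low yield array has what it needs, with 1.003 for line. The high yield array scores 0.369 for line, between 0.01 and 0.31 in low and 0.94 and 0.96 in high yield 5-6 mm arrays, so a wrong label there cannot be told apart from a mixed sample. No biological explanation was tested.

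Of the 389 probe sets whose parental difference changed between the years, 328 were called between the parents in 2007 and not in 2008, and 33 in 2008 and not in 2007. Without such a change 416 were called in both years. Separate normalization stays open. Archer moved further than Minsoy at 81.4% of the 328 probe sets (median change 1.42 against 0.54). They were chosen for a changed difference, so that 1 line has to move further. Archer was the higher line at 215 of them, and an effect that depends on the signal level was not tested. Off-type plants in the 2007 Archer row stay open. Of the 328 probe sets 45.7% were called between the recombinant lines, against 9.09% of the 33 of 2008 alone (Fisher's exact p = 2.43e-05). The recombinant lines also grew in 2007 and share its stage offset, which could raise the first share. The exact test counts probe sets as independent, which they are not, so it decides nothing. A response of the lines to the season may be the source: called genes lay no closer along the chromosomes than random ones (10 pairs, 8.92 permuted, permutation p = 0.391), but its control in the recombinant lines showed no closeness either (permutation p = 0.553), so it decides nothing. Genes called in both years did cluster (21 pairs, 11.9 permuted, permutation p = 0.0134). In a second test, added after that one, 57.7% of neighbouring pairs shared their 2008 state (permutation p = 0.629), while 63.1% did between the recombinant lines (permutation p = 0.0146). A reversed difference was a lost state in 2008, while its sign was ignored between the recombinant lines. Plants of the 2008 Archer rows with Minsoy alleles at a part of the genes could also be the source. In a test added last 29.5% of 166 genes kept 0.25 to 0.75 of the 2007 difference, against 43.4% between the recombinant lines (Fisher's exact p = 0.012). The sign of the difference counted in 2008 and was ignored between the recombinant lines, so these shares are not the same measure. That test too counts genes as independent, which they are not. On 100 markers chosen in 2007 all Archer arrays of 2008 had median scores from -0.03 to 0.07, near 0 for Minsoy 2007 and above the Minsoy arrays of their own set (-0.21 to -0.11). Both explanations allow this, while the 416 probe sets above kept a difference in 2008. Response to the season and Minsoy alleles stay open, with 57.7% and 29.5% as their test values, as do separate normalization and off-type plants.

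Other splits of the arrays exclude chance for Archer against Minsoy over the stages (1 of 100 splits as large for 2630, highest other 360). They do so at 2 mm (1 for 608, other 77) and at 3.5 mm (1 for 616, other 12). At 5-6 mm 4 of 100 splits were as large (1602, other 2206), so chance is less firmly excluded there. The larger count of another split at 5-6 mm points to a structure of the samples. For shared direction 1 of 100 splits was as large (535, other 1), but only the parents' arrays were shuffled. That repeats the test of the parental calls and decides nothing about shared direction or the stage offset. The splits also exclude chance for the change of the parental difference with year (1 for 389, other 93), less firmly so in the planting pair splits below. They do so for the stage comparisons (1 each, for 7335, other 3798, for 14614, other 6552, and for 16540, other 8161). They do not exclude chance for the high against low yield line over the stages (7; 1421, other 7295, which points to a structure of the samples), or for its change with stage (9; 312, other 704). For the change of the parental difference with stage 3 of 100 splits were as large (15, other 82, which points to a structure of the samples). Among 100 splits that part every planting pair of 2008, drawn after the results were seen, 7 were (other 134), so chance is not excluded there. Such splits gave 1, 1, 1 and 3 as large for the parents over the stages and at each stage (others 41, 30, 90 and 3124), 2 for the change with year (other 1651, again a structure of the samples), 1 for shared direction (other 0) and 79 for the lists between the parents (other 8). Nor do the first splits exclude chance for the lists called between the parents (77; 1, other 7), the recombinant lines (100; 0, other 9; limma gave 0 lists, with 4190 probe sets at an unadjusted p under 0.05) and the stages (11; 6, other 10). High against low yield at single stages has too few splits (10): 2085 at 2 mm (1 as large, highest other 152), 440 at 3.5 mm (4, other 6611, a structure of the samples) and, by limma, 0 at 5-6 mm (10, other 15; 1115 at an unadjusted p under 0.05).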

How the results depend on the processing

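Chosen after seeing the data were the fits without 4 doubted arrays, with an averaged pair, with the actin covariate and with the blocks within set and stage or with 2008 alone, and the estimator of the array weights; for each change given, unless fewer probe sets or arrays by construction explain it, the cause was not tested.

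Most named genes kept their direction and call: of 170 results 163 kept both without a filter, 166 with quantile normalization, 168 with centring, 163 without the 4 arrays, 158 with the pair averaged and 146 with only the arrays of a comparison. With 2007 arrays alone 115 of 127 did. With 1 array left out 8915 of 9180 values kept both, and 265 in 27 genes lost the call. Over all alternatives the calls lost most often were NAC6 (45 of 67), MYB186 (43 of 70) and MYB60 (24 of 67). After them came SCAM-4 between the parents (23 of 70), CCS52 (22 of 69) and PM12 (21 of 70). With 2008 arrays alone 38 of 127 kept both, 85 lost the call and 4 reversed: SIP1-4 (-0.073) and SIP1-3 (-0.018) between the parents, LCL3 (0.11) and GSTU17 (0.18) between stages.

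Counts are given against those of the report, with P for Archer against Minsoy and R for high against low yield. Without a filter: R at 3.5 mm 5975, 1103 of them among the probe sets otherwise tested, R at 5-6 mm 3, P change with stage 51, lists in P 3. With the stricter filter: P change with stage 2, R change with stage 207. Quantile normalization: R at 5-6 mm 3, P change with stage 23. A count is said to move when it changes by more than 1.5 times. Centring moved none, but there as with quantile normalization the larger side flipped for P at 3.5 mm (336 and 289) and 5-6 mm (765 and 865) and for 3.5 against 2 mm (3535 and 3974). The trended and robust fit moved none. Where the 2 sides were close the larger one flipped in other settings too: without a filter for P at 5-6 mm (769 and 922) and R at 3.5 mm (723 and 5252), with the stricter filter for R change with stage (114 and 93). Without the 4 arrays it flipped for P (1572 and 1672) and 3.5 against 2 mm (4559 and 4898), with actin for R at 2 mm (1033 and 1051) and 3.5 against 2 mm (3633 and 4069). With array weights it flipped for P (3314 and 3405), R at 2 mm (4221 and 4227), 3.5 against 2 mm (7323 and 7664) and R change with stage (1361 and 1319). With 1-gene probe sets it flipped for P (344 and 419; 211 and 257 at 5-6 mm), R at 2 mm (263 and 290) and both changes with stage (P 1 and 0, R 49 and 37). It also flipped with 2007 alone for P at 3.5 mm (131 and 122) and 5-6 mm (497 and 503) and with 2008 alone for P (442 and 478).

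Array weights (0.108 to 5.35) raised P to 6719 (2 mm 1822, 3.5 mm 7043, 5-6 mm 3647), R to 4756 (8448, 2791, 78), 3.5 against 2 mm to 14987. They raised changes with stage to 2140 (P) and 2680 (R), with year to 2520, and Same direction in the parents and in the recombinant lines to 1458. With 1-gene probe sets, fewer by construction: P 763 (182, 206, 468), R 395 (553, 130), stages 2127, 3863 and 4507, changes 1 (P), 86 (R) and 129 (year), Same direction in the parents and in the recombinant lines 165.

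With only the arrays of a comparison: P 1083 at 3.5 mm and 393 at 5-6 mm, R 448 (121, 59), changes 27 (P), 72 (R) and 611 (year). With 2007 alone: P 375, 253 and 1000 by stage, change with stage 23, lists 4. With 2008 alone: P 920 (244, 243, 341), change with stage 2, lists 0, stages 74, 0 (limma; 3001 at an unadjusted p under 0.05) and 1213. With an estimated correlation, with or without the 4 arrays, limma's camera called 0 lists in P and 0 between stages; with every probe set of a gene it called 4 in P, 2 in R and 13 between stages.

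Without the 4 arrays: P 1039 at 3.5 mm and 3345 at 5-6 mm, R 1322 at 2 mm and 321 at 5-6 mm, changes 83 (P) and 157 (R), lists 3 (P) and 1 (R). With the pair averaged: R at 2 mm 951, change with stage 129. With actin: P at 5-6 mm 2733, R at 3.5 mm 772 and at 5-6 mm 1.

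A replicate block moved no count: P 2611, R 1385, 5-6 against 2 mm 16527, changes 20 (P), 258 (R) and 395 (year), and R at 5-6 mm 0 (limma; 1107 at an unadjusted p under 0.05). Residuals of arrays with the same number had median correlations of 0.25 (parents 2007), 0.03 (parents 2008), 0.15 (recombinant lines) and -0.02 (stages). It lost the calls of MYB186 between the parents, VSPA and NAC6 between the recombinant lines and MYB60 for the change with year. With a block within set and stage, for differences between lines, R change with stage was 192 and R at 5-6 mm 1, and 77 of 82 named results kept direction and call; R at 3.5 mm was 491 and the lists stayed at 1 (P) and 0 (R). With a block and 2008 alone, against the 2008 counts above: P 836 (221, 218, 284), change with stage 2, lists 0, stages 11, 0 (limma; 2528 at an unadjusted p under 0.05) and 7, and 18 of 127 named results kept both.

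Leaving out 1 array gave ranges of 2129 to 3881 for P (480 to 706, 408 to 722 and 592 to 3946 by stage). For R it gave 1110 to 2131 (966 to 2836, 267 to 2650, 0 to 140). It gave 5912 to 9752, 13662 to 16564 and 15935 to 17232 between stages. It gave 8 to 691, 135 to 565 and 315 to 500 for changes with stage (P, R) and year, and 1 to 3, 0 to 3 and 6 to 6 for lists in P, R and stages. Same direction in the parents and in the recombinant lines ranged from 455 to 623. P at 3.5 mm fell to 408 without Archer 2008 replicate 3. P at 5-6 mm was 633 without Archer 2007 replicate 1, 3946 and 966 without Minsoy 2007 replicates 1 and 2, 1067 and 746 without Archer 2008 replicates 1 and 3, and 2633 and 592 without Minsoy 2008 replicates 1 and 3. R at 2 mm was 966, 986 and 1165 without high yield 2 mm replicates 1 and 2 and low yield 2 mm replicate 1. R at 3.5 mm was 267 without high yield 3.5 mm replicate 1 and 2650 without low yield 3.5 mm replicate 2. R at 5-6 mm was 1, 3, 140 and 42 without high yield 3.5 mm replicate 3, low yield 5-6 mm replicate 3, high yield 5-6 mm replicate 1 and low yield 2 mm replicate 1. R change with stage was 140, 565 and 469 without low yield 2 mm replicates 1 to 3, 135, 137 and 505 without high yield 2 mm replicates 1 to 3. It was 174 and 159 without low yield 5-6 mm replicates 1 and 2, 162 and 164 without high yield 5-6 mm replicates 2 and 3, and 487 without low yield 3.5 mm replicate 2. P change with stage was 691, 49 and 8 without Minsoy 5-6 mm 2007 replicates 1 to 3, 40 without Minsoy 3.5 mm 2007 replicate 3. It was 27 without Minsoy 5-6 mm 2008 replicate 1 or low yield 3.5 mm replicate 3, 28 without Archer 2 mm 2008 replicate 3 or low yield 2 mm replicate 1. It was 8 without Archer 2 mm 2007 replicate 2, and 9 without Minsoy 2 mm 2007 replicate 1, Archer 5-6 mm 2007 replicate 1, Archer 2 mm 2008 replicate 2 or Minsoy 2 mm 2008 replicates 2 and 3. Lists in P were 2 or 3 without any of 25 arrays, and in R 2 and 3 without low yield 5-6 mm replicate 1 and 3.5 mm replicate 3.

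Comparisons of 2008 with 2007 in the parents and of each recombinant line with both parents were not run, since the sets were normalized apart; many probe sets lie at the floor of the parental sets, where differences are not measurable.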

Other observations

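BZIP94 had a mean of 7.63 in the high yield line and 3.51 in the low yield line, the latter with 3 arrays of 5.28 to 6.95 and 6 of 2.05 to 2.71. In the parents it lay at or near the floor (1.96 to 2.03) in all arrays but Archer 5-6 mm 2007 replicate 3 (5.25). Levels are not comparable between sets.

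On markers chosen in 2008 some Minsoy 2007 arrays scored partly towards Archer: 5-6 mm replicates 3 and 2 (0.62 and 0.32), 3.5 mm replicate 2 (0.34) and 2 mm replicate 2 (0.26), against 0 for Minsoy and 1 for Archer. Low yield line 3.5 mm replicate 3, whose description names the other line, scored 0.02 on the scale of the recombinant lines, with the low yield line. High yield 3.5 mm replicate 3 and low yield 3.5 mm replicate 2 had late stage scores, 3.77 and 3.61.

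The most alike arrays of the series were high yield 2 mm replicates 1 and 2 (r = 0.9974 across probe sets), then low yield 5-6 mm replicate 3 with high yield 5-6 mm replicate 1 (0.9965) and high yield 5-6 mm replicate 2 with low yield 2 mm replicate 1 (0.9963). The next pair had 0.9926. Probe sets are not independent of one another, and whether any of these pairs share an RNA sample is not known.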
